A study of Mus musculus with 20 samples.

How the data were processed

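RNA (200 ng per sample, biotin-labelled cRNA) was hybridized to 20 Affymetrix mouse arrays: 16 from squamous cell carcinomas (4 genotypes, 2 tumours each, a CD34low and a CD34high fraction per tumour) and 4 from normal skin cells (2 epidermal progenitor, 2 hair follicle bulge). Tumour cells had been selected for high CD29 and CD49f, given a retroviral reporter and grafted, and the fractions were sorted from reporter-positive cells.

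The deposited table holds probe set intensity on a linear scale, which the authors derived by RMA per the submitters' processing notes; the RMA version is not given in the sources used here. The values themselves show a lowest value of 20 and a highest of 20000. Each deposited probe set also reaches at least 120 somewhere, spans at least 100 between its lowest and highest array and varies at least 2-fold, so dim or steady genes had been filtered out before deposit. Genes removed there, Ptk2 possibly among them, are not analysed here. The log2 was taken, as the planned models assume log2 values. No columns of the table were left unmapped to a sample (0).

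Of 15208 probe sets, 50 controls, 366 with several gene symbols and 901 without a gene in the platform annotation were left out, and 13891 with 1 symbol were kept. Symbols were checked through Entrez IDs against a gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols. For the 3199 genes with over 1 probe set, the probe set with the highest mean over all arrays was taken, which gave 9248 genes. A fold against a group at the floor or the ceiling in all its arrays is a lower bound and is given as "at least". Interaction values with groups at the floor are not exact and bound neither side. Median intensity per array was 188 to 220, and 3.52 to 5.46% of probe sets of an array sat at the floor.

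Both fractions of a tumour were averaged to 1 value, which left 12 units in 6 groups (4 genotypes and 2 normal populations, 2 units each). A linear model over these was fitted with limma 3.58.1 in R 4.3.3, with eBayes and Benjamini-Hochberg adjustment over all genes of a comparison, and adjusted p under 0.05 counted as passing. Comparisons were WT SCC against each normal population, bulge against epidermal progenitor, TbRII KO, FAK KO and dKO against WT, dKO against TbRII KO, and the interaction of TbRII and FAK loss. CD34high against CD34low was fitted over 20 arrays in 10 groups as the mean over 4 genotypes, and the genotype effect on the fraction difference by a moderated F test on within-tumour differences (9185 genes with any variation). Deviations of the fractions of 1 tumour from their group means correlated at 0.786 in WT, 0.799 in TbRII KO, 0.663 in dKO and 0.787 in FAK KO, so fractions of a tumour are paired, and values with the tumour as block are given beside the unblocked ones. Exact sign-flip tests over 8 tumours were two-sided.

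Gene lists were tested with limma camera (preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison), and beside it with an estimated correlation and with fry. The 23 lists were hair follicle bulge stem cell, terminal epidermal differentiation, basal keratinocyte and hemidesmosome, hyperproliferative and simple-epithelial keratins, cell cycle, mesenchymal and EMT, TGF-beta response, integrins and focal adhesion, Wnt signalling, Notch signalling, hypoxia and glycolysis, matrix proteases and invasion, inflammatory cytokines, interferon response, immediate early, NRF2 and glutathione, and markers of leukocytes and macrophages, fibroblasts, endothelium, melanocytes, sebaceous gland, hair matrix and shaft, and Langerhans and dendritic cells. Some genes sit on a pair of lists (Itga6, Itgb1 and Itga3 on basal and integrin lists, Twist2 on mesenchymal and fibroblast lists).

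Genes named in the text follow a rule: the targeted genes Tgfbr2 and Ptk2 and the sorting genes Cd34, Itga6 and Itgb1 always. To these were added, per comparison, the 8 largest rises and 8 largest falls that passed without overlap between replicates of both sides, predicted genes passed over. From each list up to 4 passing members with the smallest adjusted p were taken, or the 1 with the smallest p where none passed. Groups, models, lists, this rule and the alternatives were set before the data were examined, except where later choices are stated.

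Alternatives were a 2-fold threshold, the mean of a gene's probe sets, leaving out the 40% of genes with the lowest mean, quantile normalization, eBayes with trend and robust options, only the compared groups in the fit, replicate number as block, the 20 arrays as separate units, the tumour as random block (consensus correlation 0.706), a single fraction, WT tumours only, the tumour block, and each tumour or array left out. Leaving out 1 of the 2 samples of a compared group leaves a single sample there, whose spread is taken from the other groups, so a gene that still passes is shown not to rest on the sample left out and gains no further support. Chosen after seeing the data were the mean of the leukocyte and macrophage markers as covariate and leaving out tumours in the genotype test of the fractions.

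Models were tested on simulated data with the same design (9248 genes, 200 changed). Of 100 genes changed 2-fold and 100 changed 4-fold, 5% and 57% were recovered for TbRII KO against WT, 2% and 64% for WT SCC against epidermal progenitor, 74% and 99% between fractions without the block, and 89% and 100% with it (11 unchanged genes also passed). Recovery was 0% and 9% for the interaction, and 0% and 53% for the genotype effect on fractions. Camera called 5 of 5 shifted lists and 0 of 15 unshifted ones. The simulated genes varied independently of each other, so this does not test lists whose genes vary together. A 2-fold change between genotypes is therefore mostly missed with 2 tumours per group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.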

Results

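Gene expression was measured on 20 Affymetrix arrays from mouse skin. Of these, 16 came from grafted squamous cell carcinomas (SCC) of 4 genotypes, with 2 tumours per genotype and a CD34low and a CD34high fraction sorted from each tumour. The genotypes were WT (floxed Tgfbr2 without Cre), TbRII KO, FAK KO and the TbRII/FAK double knock-out (dKO). The other 4 arrays held normal epidermal progenitors (n = 2) and hair follicle bulge cells (n = 2). Median intensity per array lay between 188 and 220, and 3.52 to 5.46% of the probe sets of an array sat at the lowest value of 20. Changes are log2 differences between groups of tumours (both fractions of a tumour averaged) or normal arrays, with their standard error (SE). The Cd34 value of a tumour averages fractions sorted by CD34. The sort thus sets it in part, and comparisons of tumours do not test effects on Cd34. Selection of the cells for high CD29 (Itgb1) and CD49f (Itga6) before grafting may likewise bear on those genes. A gene passed when its limma adjusted p was under 0.05 among 9248 genes. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical, and 2 tumours or arrays per group limit the precision. The spread of a gene is estimated over all 6 groups together. Replicate arrays of a normal population correlated at a median of 0.990, against 0.914 for those of an SCC group. The p-values between genotypes can therefore rest on a smaller spread than that between the compared tumours.

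Normal cells and tumours separated along the first principal component, which held 36.8% of the variance, and the second (13.9%) parted the TbRII KO tumours from the dKO tumours. Both fractions of 1 tumour had a median correlation of 0.969 over 8 pairs, against 0.914 for replicate arrays of an SCC group and 0.838 for arrays of different genotypes. Correlations of SCC arrays with epidermal progenitors had a median of 0.705 and with bulge cells 0.651.

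**Figure D1:**
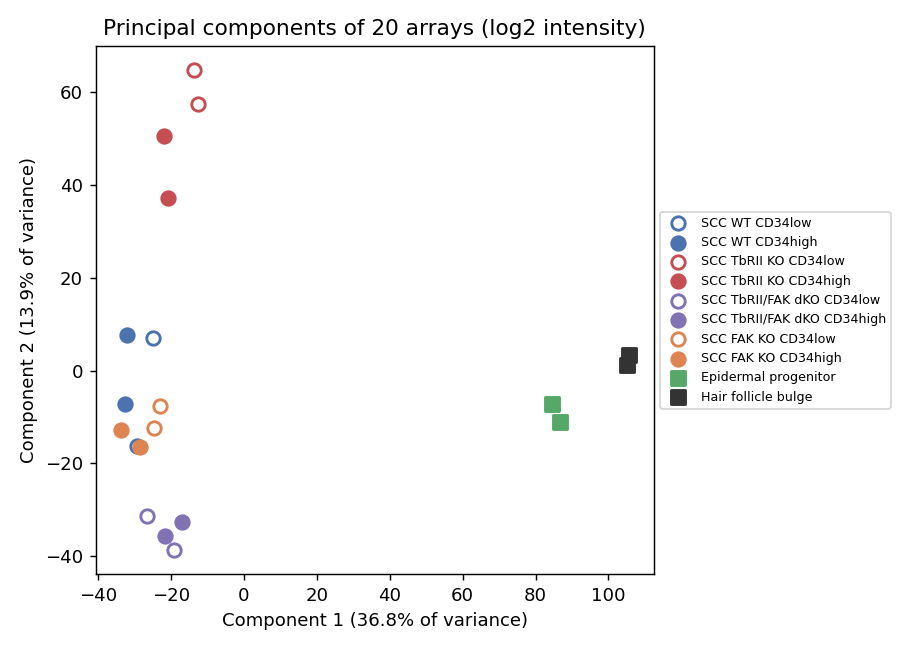
Each dot is 1 of 20 arrays on the first 2 principal components of log2 intensity (36.8% and 13.9% of the variance), coloured by group. Normal cells lie apart from SCC on component 1, and TbRII KO and dKO tumours lie at opposite ends of component 2.

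What sets WT SCC apart from epidermal progenitors was asked first, with 2 tumours against 2 arrays. Gsta4, a glutathione transferase for lipid peroxidation products, rose 185-fold (log2 7.53, SE 0.40, adjusted p = 2.68e-06), to an intensity of 11760 from 63.7. Stress and simple-epithelial keratins rose as well: Krt6a 119-fold (log2 6.90, SE 0.38), Krt6b at least 88.7-fold (log2 6.47, SE 0.64) and Krt18 at least 93.3-fold (log2 6.54, SE 0.66). The suprabasal keratin Krt1 fell by 8.12 on the log2 scale (SE 0.82, adjusted p = 9.14e-05), from 8648 to 31.0, and Krt77 by 7.95 (SE 0.20). The desmosomal cadherin Dsg1a was at least 52.1-fold lower and Dsc1 at least 19.4-fold lower, while the envelope precursor Sprr1b was at least 81.1-fold higher. The other largest rises were those of Cald1 (at least 150-fold), the neuropeptide gene Calcb (log2 7.12), Prkg2 (6.92), the chromatin protein gene Hmga2 (6.55) and Wfdc2 (6.50). Capns2 (-8.00), Oas1f (-7.59), Tmem45a (-7.47), Bbox1 (-7.16), Mt4 (-6.79) and Clca3a2 (at least 105-fold lower) had the other largest falls.

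Mesenchymal regulators and matrix genes rose in WT SCC over epidermal progenitors, some of them also on the fibroblast list (Twist2, Col3a1, Col1a2 and Col1a1). The mean log2 level of that list was 6.34 to 7.88 in WT SCC arrays, against 4.63 and 4.89 in epidermal progenitors. Whether fibroblast RNA among the sorted cells gave these rises was not tested, here or against the bulge. Twist1 was at least 14.1-fold higher, Foxc2 at least 15.4-fold higher, Twist2 14.1-fold (log2 3.82, SE 0.53), and the collagen gene Col3a1 34.2-fold (log2 5.09, SE 0.61) beside Col1a2 (20.7-fold) and Col1a1 (11.9-fold). Genes of low-oxygen metabolism rose with them, Vegfa 15.8-fold (SE 0.41) and Hk2 7.47-fold (SE 0.32), as did the glutathione synthesis gene Gclm (27.3-fold, SE 0.66) and the invasion genes Timp1 (25.7-fold), Tnc (34.5-fold) and Plaur (6.50-fold). Chemokine genes Cxcl1 (13.7-fold) and Cxcl2 (at least 30.9-fold) rose, while the alarmin Il33 fell by 5.94 (SE 0.37) and the Wnt feedback gene Axin2 by 3.62 (SE 0.37). The spindle checkpoint gene Bub1 rose 8.31-fold (SE 0.33), Cdkn2b 4.76-fold, the macrophage gene Cd68 5.13-fold and the actin cross-linker Actn1 8.05-fold, whereas Tgfbi (-2.14), Gata3 (-3.78), Egr2 (-3.41), Mitf (-1.73), Cd83 (-2.49) and Usp18 (-2.71) fell. Among the sorting markers, the integrin gene Itgb1 rose 3.83-fold (SE 0.32, adjusted p = 0.0018). Cd34 (2.34, SE 0.97, adjusted p = 0.0958), Itga6 (0.45, SE 0.26, adjusted p = 0.214) and Tgfbr2 (-1.10, SE 0.51, adjusted p = 0.132) did not pass.

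By list, hyperproliferative and simple-epithelial keratins shifted up in this comparison (6 higher, 0 lower and 5 not passing of 11, 6 and 0 adjusted over the list alone, camera adjusted p = 0.000449, and 0.115 with an estimated correlation). Mesenchymal and EMT genes rose too (8 of 12 higher, 0 lower, the same 8 and 0 by count over the list alone, adjusted p = 0.000449, and 0.261 with an estimated correlation). Hypoxia and glycolysis (8 higher and 1 lower of 15, also over the list alone, adjusted p = 0.000565, and 0.586 with an estimated correlation), NRF2 and glutathione (4 higher of 10, 4 alone; 0.0103, and 0.586) and fibroblast markers (6 higher of 11, 6 alone; 0.00226, and 0.586) passed only with the preset correlation. Terminal differentiation had 2 higher and 7 lower of 18 (3 and 8 alone, adjusted p = 0.0851) and basal keratinocyte and hemidesmosome genes 1 and 4 of 14 (3 and 5 alone; 0.356). Matrix proteases had 5 higher of 12 (0.0748), cell cycle 4 of 24 (0.0851), immediate early genes 1 higher and 2 lower of 12 (0.0851), integrins and focal adhesion 4 of 18 (0.105), cytokines 6 higher and 2 lower of 13 (0.197) and TGF-beta response 4 higher and 1 lower of 12 (0.243). Wnt (2 higher, 4 lower of 12; 0.348), Notch (0 and 1 of 9; 0.684), interferon (1 and 1 of 5; 0.437) and bulge stem cell genes (1 and 3 of 15; 0.415) did not shift as lists. Neither did markers of leukocytes (3 and 1 of 12; 0.415, median 0.17 and negative after quantile normalization), endothelium (0 of 2 by limma; 0.974), melanocytes (0 and 1 of 2; 0.348), sebaceous gland (1 and 1 of 4; 0.437), hair matrix and shaft (0 and 1 of 4; 0.156) or Langerhans and dendritic cells (0 and 1 of 4; 0.255).

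In all, 2865 genes passed between WT SCC and epidermal progenitors, 1391 higher and 1474 lower. Of 80 named genes that passed, 57 passed under every alternative. Between 1320 and 3343 genes passed with 1 tumour or normal array left out: 1320 without epidermal progenitor array 1 and 1578 without array 2. The tumours were grafted, infected and sorted on other markers than the normal cells, so handling and cell state change together here.

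Against the hair follicle bulge, WT SCC had lower levels of bulge stem cell genes and higher levels of proliferation genes, again with 2 tumours against 2 arrays. Lgr5 was at the floor of 20 in epidermal progenitors as well, so low bulge genes do not set the tumours apart from all normal cells. The bulge regulators Lhx2 (log2 -7.29, SE 0.29, at least 157-fold lower) and Lgr5 (-6.70, SE 0.20, adjusted p = 9.44e-08, at least 104-fold lower) fell to the floor, and the quiescence factor Nfatc1 fell by 4.62 (SE 0.24). Cd34 was 34.2-fold lower in tumours (SE 0.97, adjusted p = 0.00279, intensity 277 against 9491). The proliferation genes Mki67 (37-fold, SE 0.46), Top2a (24.6-fold, SE 0.34), Bub1 (at least 21.9-fold) and Birc5 (16.2-fold) rose. Connective tissue growth factor Ccn2 fell 102-fold (log2 -6.67, SE 0.57), as did the Wnt genes Fzd7 (12.4-fold lower) and Sfrp1 (48.1-fold lower). Itga6 (3.66-fold, SE 0.26, adjusted p = 0.000461) and Itgb1 (3.69-fold, SE 0.32, adjusted p = 0.0015) rose, and Tgfbr2 did not pass (0.04, SE 0.51, adjusted p = 0.961).

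The largest rises over the bulge were again those of Gsta4 (log2 8.09), Calcb (8.03), Prkg2 (7.04), Wfdc2 (7.02), Krt18 (at least 93.3-fold) and Krt6b (at least 88.7-fold), joined by Anxa3 (at least 104-fold) and Ptprz1 (at least 89.2-fold), the last 4 at the floor in the bulge. Krt77 (-8.19), Tgm5 (-8.07), the chemokine gene Cxcl14 (-7.93), Capns2 (-7.86), Krt1 (-7.52), Krt24 (at least 160-fold lower) and Shisa2 (at least 128-fold lower) fell. Hmga2 rose 63-fold (SE 0.63), Twist1 at least 14.1-fold, Col3a1 at least 51-fold, Vegfa 27.6-fold (SE 0.41), Pgk1 5.94-fold, Cxcl1 42.2-fold and Ptgs2, the inducible prostaglandin synthase, 19.7-fold (SE 0.42). The redox genes Gsr (8.63-fold) and Txnrd1 (5.27-fold), Oas1a (6.80-fold), the circadian repressor gene Bhlhe40 (9.35-fold), Krt16 (13.8-fold), Itga3 (3.08-fold) and Timp1 (19.3-fold) rose. The hair shaft regulator gene Hoxc13 fell by 4.55 (SE 0.26) and Mitf by 6.14 (SE 0.25, adjusted p = 2.62e-07; 1 of 2 melanocyte markers lower, camera adjusted p = 0.126), beside the fibroblast gene Fbln1 (-4.10) and Lor (-4.90).

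Bulge stem cell genes fell as a list (0 higher, 13 lower and 2 not passing of 15, 14 lower over the list alone, camera adjusted p = 1.26e-08, and 0.0284 with an estimated correlation). Cell cycle genes rose (23 of 24 higher, 23 alone, adjusted p = 6.48e-12, and 0.281 with an estimated correlation), and hair matrix and shaft genes fell (4 of 4 lower, 4 alone; 0.000579, and 0.0868 with an estimated correlation). Passing only with the preset correlation, keratins (5 of 11 higher, 6 alone; 0.00688, and 0.121), hypoxia (10 of 15, 11 alone; 0.000579, and 0.444), cytokines (6 higher, 1 lower of 13, 7 and 1 alone; 0.0204, and 0.346), mesenchymal genes (7 and 2 of 12, 8 and 2 alone; 0.0291, and 0.391), matrix proteases (6 of 12, 6 alone; 0.0291, and 0.444) and NRF2 genes (4 and 1 of 10; 0.0291, and 0.444) shifted up. Wnt genes had 3 higher and 5 lower of 12 (adjusted p = 0.0811), interferon genes 4 and 1 of 5 (0.314) and terminal differentiation 2 and 9 of 18 (0.107). TGF-beta response genes had 4 higher and 4 lower of 12 (adjusted p = 0.83, a median of 0.31 but a mean of -0.05), and leukocyte markers 2 higher of 12 (0.83, a median of -0.05 but a mean of 0.26).

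WT SCC and bulge differed in 3625 genes, 1812 higher and 1813 lower in SCC. Of 80 named genes that passed, 66 passed under every alternative. Leaving out 1 tumour or array gave 2124 to 4050 genes, with 2124 without bulge array 1 or array 2. Genes higher in WT SCC than in both normal populations numbered 1064 (273 expected if independent), and genes lower than in both 1066 (289 expected), with 35 in opposite directions. Simulated unchanged groups gave a mean overlap of 0.02 (highest 1, 50 simulations), which is chance with no effect and does not measure the share of common samples. The same WT tumours serve in both comparisons and are too few to split, and part of the excess may come from these shared controls.

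How the normal populations differ gives the reference for those changes. Cd34, which marks the bulge, was 173-fold higher there than in epidermal progenitors (log2 7.44, SE 0.97, adjusted p = 0.000726, intensity 9491 against 54.7, n = 2 and 2). The stem cell genes Lgr5 (at least 104-fold, SE 0.20), Lhx2 (79.6-fold, SE 0.29), Fgf18 (at least 32.9-fold, SE 0.33), Ltbp2 (at least 69.9-fold, SE 0.48) and Nfatc1 (9-fold, SE 0.24) rose in the bulge. Wnt-side genes Fzd7 (15.4-fold) and Dkk3 (17.2-fold), and Ccn2 (57.9-fold, SE 0.57), were higher there as well, along with Krt6a (60.1-fold), S100a4 (at least 21.6-fold, at the ceiling in the bulge), the pigment cell gene Mitf (21.3-fold) and Hoxc13 (22.8-fold). Further large rises were those of Wfdc3 (log2 6.33), Col8a2 (6.25), Tgm5 (6.10) and Shisa2 (6.08). Mitotic genes were lower in the bulge, Ube2c by 16.1-fold, Ccnb2 by 14.3-fold (SE 0.37), Nusap1 by 14.9-fold and Top2a by 11.3-fold (SE 0.34), together with Il33 (22.1-fold lower), Il22ra2 (-4.12), Arhgap25 (-4.04) and Tnfrsf19 (-3.99). Itga6 was lower in the bulge (log2 -1.42, SE 0.26, adjusted p = 0.00583), which did not pass without epidermal progenitor array 2 or bulge array 1 (adjusted p up to 0.0665). Itgb1 (0.05, SE 0.32, adjusted p = 0.988) and Tgfbr2 (-1.15, SE 0.51, adjusted p = 0.223) did not pass.

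Over lists, bulge stem cell genes rose in the bulge (12 higher, 0 lower, 3 not passing of 15, 12 alone, camera adjusted p = 2.6e-16, and 0.00479 with an estimated correlation). Cell cycle genes fell (18 of 24 lower, 21 alone; 9.06e-18, and 0.18 with an estimated correlation). Hair matrix genes (3 higher, 1 lower of 4; 0.00827, and 0.18 with an estimated correlation) shifted up, and cytokines (0 higher, 3 lower of 13; 0.0268, and 0.357) and immediate early genes (none of 12 by limma, 5 lower alone; 0.00827, and 0.732) shifted down. Wnt genes split into 5 higher and 5 lower of 12 (0.359), TGF-beta response genes into 3 and 1 of 12 (0.215). The 1052 genes that passed held 535 higher and 517 lower, and 41 of 58 named genes that passed did so under every alternative. From 511 to 1445 genes passed with 1 tumour or array left out: 536 without epidermal progenitor array 1, 516 without array 2, 511 without bulge array 1 and 530 without array 2.

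What TbRII loss changes in SCC was asked next, with 2 TbRII KO against 2 WT tumours. The targeted gene Tgfbr2 read higher, not lower, in TbRII KO tumours without passing (log2 1.80, SE 0.51, adjusted p = 0.0745, intensity 2409 against 692). Its 1 probe set has no stated position relative to the deleted exon, so this value does not test the deletion. The secreted growth factor binding protein gene Igfbp6 rose 210-fold (log2 7.72, SE 0.57, adjusted p = 9e-05), the matrix protein gene Mgp 81.9-fold (log2 6.36, SE 0.35) and the sphingosine receptor gene S1pr3 63.2-fold (log2 5.98, SE 0.30). Calcb, which encodes a neuropeptide, was 172-fold lower (log2 -7.43, SE 0.54, adjusted p = 8.28e-05), and the Wnt antagonist gene Dkk3 16.6-fold lower (log2 -4.05, SE 0.59). Xist, which silences the X chromosome in female cells, rose 70.7-fold (log2 6.14, SE 0.51). Tenm2 (at least 66.6-fold), Bbs7 (53.5-fold), Kcnj15 (at least 44.1-fold), Aldh3a1 (34.9-fold) and the MHC class II gene H2-Eb1 (18.8-fold) rose too. Other class II genes did not rise with H2-Eb1. H2-Aa read 150.5 and 271.6 in TbRII KO tumours against 146.2 and 820 in WT tumours, and H2-Ab1 88.5 and 105 against 112.3 and 1100.9.

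The EMT regulator Zeb1 rose 5.93-fold in TbRII KO tumours (log2 2.57, SE 0.32, adjusted p = 0.00184, intensity 125 against 21.1), and the fibroblast marker Pdgfra 4.95-fold (log2 2.31, SE 0.29). Within TbRII KO tumours Zeb1 was lower in CD34high than in CD34low fractions (mean log2 difference -2.16). That difference was -0.15 in WT, 0.05 in dKO and 0.28 in FAK KO tumours (moderated F test over genotypes, adjusted p = 0.193). Zeb1 did not pass with only these 2 genotypes in the fit (adjusted p = 0.0809) or with CD34high arrays alone (0.109), nor did Pdgfra (0.0688 and 0.378, and 0.0871 with the tumour as a random block). Zeb2 (3.55-fold, adjusted p = 0.0292) and S100a4 (4.22-fold, adjusted p = 0.0149) rose, and the EMT regulator Snai2 fell (2.91-fold lower, adjusted p = 0.0165). Some basal and simple-epithelial genes fell: Krt18 11.9-fold lower (SE 0.66), the laminin genes Lama3 3.26-fold (SE 0.31) and Lamb3 6.47-fold lower (SE 0.53), and the tight junction gene Cldn8 at least 33.5-fold lower (SE 0.98). Each of these calls failed when some TbRII KO tumour was left out: Krt18 (adjusted p = 0.0979) and Snai2 (0.0832) without tumour 1, Lama3 (0.0664) and Lamb3 (0.102) without tumour 2, S100a4 (up to 0.0832) and Cldn8 (up to 0.0892) without either, and Zeb2 (up to 0.132) in 6 of the 12 leave-outs. The chemokine gene Ppbp (-4.63; adjusted p = 0.0945 without tumour 1), Pdpn (-4.56; 0.0983 without tumour 1), Tslp (at least 29.3-fold lower, up to 0.181), Cstf2t (-4.27; up to 0.124) and the desmoglein gene Dsg2 (at least 17.8-fold lower, up to 0.166) completed the largest falls. Csf1 (3.03-fold) and the hypoxia gene Car9 (9.83-fold) rose and Usp18 fell (at least 4.60-fold lower) with any 1 tumour or array left out. Cd34 (0.13, SE 0.97, adjusted p = 0.966), Itga6 (-0.80, SE 0.26, adjusted p = 0.113) and Itgb1 (0.08, adjusted p = 0.918) did not pass.

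Pigment cell genes rose as a pair, Mlana 10.5-fold (SE 0.26) and Mitf 6.22-fold (SE 0.25; list of 2, 2 alone, camera adjusted p = 0.000315, and 0.194 with an estimated correlation). Basal keratinocyte genes fell (0 higher, 3 lower and 11 not passing of 14, 5 lower alone, adjusted p = 0.0046, and 0.468 with an estimated correlation), as did interferon response genes (1 of 5 lower, 4 alone; 0.00261, and 0.53 with an estimated correlation). Keratins (0 higher, 1 lower of 11, 3 lower alone, adjusted p = 0.0675), integrins (0 and 2 of 18, 5 lower alone; 0.0675) and mesenchymal genes (3 higher, 1 lower of 12, 5 and 3 alone; 0.596) did not pass. TGF-beta response genes had 0 higher and 2 lower of 12 (adjusted p = 0.596, median -0.03, positive after quantile normalization). Fibroblast (1 higher of 11; 0.596) and leukocyte markers (1 higher of 12; 0.747) stayed without a shift, and so did the cell cycle list (0 of 24 by limma; 0.775).

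TbRII KO and WT tumours differed in 570 genes, 338 higher and 232 lower, and 13 of 38 named genes that passed did so under every alternative. With only the WT and TbRII KO tumours in the fit 69 passed. From 283 to 1482 passed with 1 tumour or array left out: 283 and 352 without TbRII KO tumours 1 and 2, 1482 without WT tumour 2, 365 without either epidermal progenitor array and 358 without either bulge array. CD34low arrays alone gave 768 genes and CD34high arrays alone 292.

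**Figure D2:**
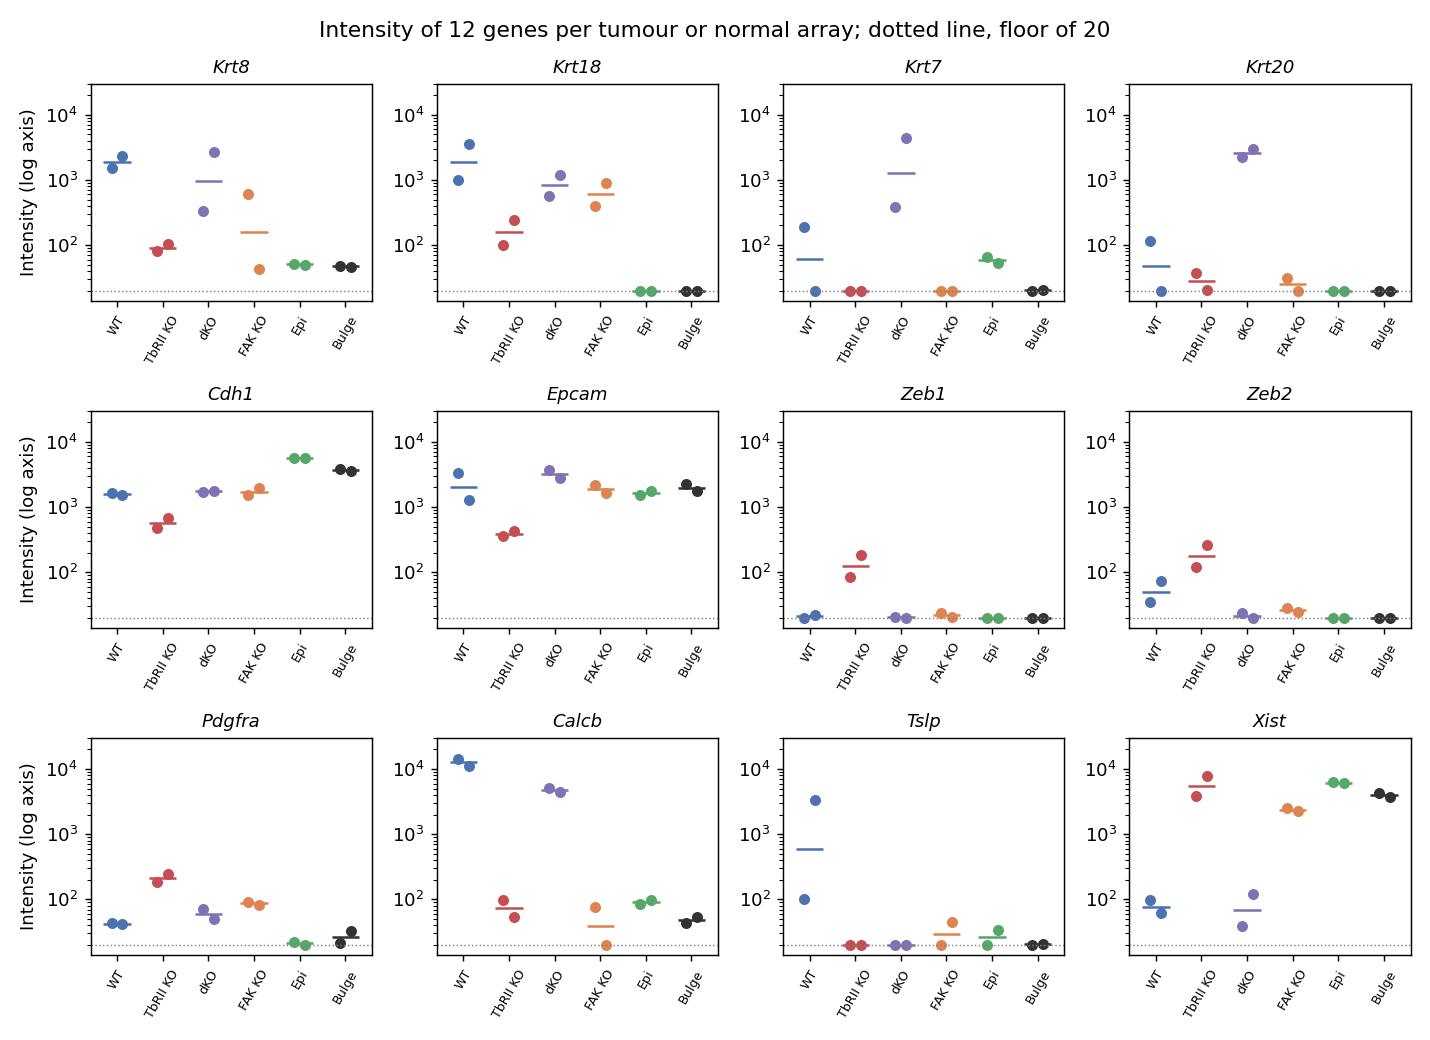
Intensity (log axis) of 12 genes, with a dot per tumour or normal array, a line at the geometric mean of each group and a dotted line at the floor of 20. Calcb is high in WT and dKO tumours only (12674 and 4719), and Xist is high in TbRII KO, FAK KO and normal cells.

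Effects of FAK loss alone were smaller in number, with 2 FAK KO against 2 WT tumours. The targeted gene Ptk2 is not analysed here. Calcb was 324-fold lower (log2 -8.34, SE 0.54, adjusted p = 0.000333), the pyrimidine catabolism gene Dpyd at least 16.7-fold lower (SE 0.29), the kinase gene Nrk at least 9.11-fold lower (SE 0.22) and the growth cone gene Gap43 11.8-fold lower (SE 0.31). The epithelial transcription factor gene Gata3 fell by 2.82 (SE 0.32, adjusted p = 0.00859), while Ly6d (14.2-fold, SE 0.43) and Xist (30.6-fold, SE 0.51) rose. These 7 genes passed with any 1 tumour or array left out. Hmga2 (23.8-fold lower, SE 0.63) and the epithelial cytokine gene Il1f9 (12.6-fold higher, SE 0.50) passed except without any 1 normal array (adjusted p up to 0.0542). Other large changes that passed, but not in 5 to 9 of the leave-outs, were Lypd6b (3.83), Il1rl2 (3.02), Capns2 (2.87), Ms4a7 (2.75), F13a1 (2.59), Tm4sf1 (-3.53), Gpm6b (-3.19) and Spin4 (-3.03). Cd34 (-2.04, SE 0.97, adjusted p = 0.364), Itga6 (-0.30, adjusted p = 0.618), Itgb1 (-0.02, adjusted p = 1) and Tgfbr2 (0.27, adjusted p = 0.849) did not pass.

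Macrophage genes rose in FAK KO tumours: C1qb 4.34-fold (SE 0.37, adjusted p = 0.0399), C1qa 5.56-fold (SE 0.46, 0.0481) and Laptm5 4.77-fold (SE 0.41, 0.0437). Their adjusted p reached 0.106, 0.158 and 0.122 with 1 tumour or array left out. Leukocyte and macrophage markers had 3 higher, 0 lower and 9 not passing of 12 (9 higher over the list alone, camera adjusted p = 2.13e-07, and 0.374 with an estimated correlation). Fibroblast markers moved with them (0 of 11 over all genes by limma, 6 higher and 1 lower alone; 0.000309, and 0.374 with an estimated correlation). Terminal differentiation (1 of 18 higher, Dsc1 at least 3.20-fold, 5 alone; 0.00709, and 0.479), cell cycle (0 of 24, also alone; 0.00904, and 0.611) and cytokine genes (0 of 13, 2 higher and 1 lower alone; 0.0287, and 0.374) shifted up only with the preset correlation. Integrins and focal adhesion (0 of 18, 4 lower alone; 0.000524, and 0.374 with an estimated correlation) and mesenchymal genes (0 higher and 1 lower of 12, 2 and 5 alone; 0.00536, and 0.374) shifted down. Matrix proteases (0 of 12, 4 higher alone, adjusted p = 0.32) and keratins (0 of 11, 2 higher and 1 lower alone; 0.643) did not shift.

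FAK KO and WT tumours differed in 70 genes, 24 higher and 46 lower, where 1387 had an unadjusted p under 0.05. With only FAK KO and WT tumours in the fit, limma passed 0 genes (533 unadjusted), so none of the 21 named genes passed under every alternative, and 16 passed with the macrophage marker mean as covariate, 6 of them among the 70. Between 9 and 555 passed with 1 tumour or array left out: 408 and 555 without WT tumours 1 and 2, 268 and 22 without FAK KO tumours 1 and 2, 110 without either dKO tumour and 9 without any of the 4 normal arrays.

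Loss of both genes was compared with WT, again in 2 tumours each. Tgfbr2 did not pass (0.18, SE 0.51, adjusted p = 0.841), and Ptk2 is not analysed here. The simple-epithelial keratin Krt20 rose 53-fold (log2 5.73, SE 0.66, adjusted p = 0.00792), the tight junction gene Cldn3 17.8-fold (log2 4.15, SE 0.36, adjusted p = 0.0025), Pdlim4 13.4-fold (SE 0.35), the water channel gene Aqp5 10.7-fold (SE 0.44), Ly6d 9.91-fold (SE 0.43) and the alarmin Il33 9.06-fold (SE 0.37). Gata3 was 7.90-fold lower (SE 0.32), Spin4 12.8-fold (SE 0.46) and Ang 11.4-fold lower (SE 0.48). These 9 genes and Laptm5 (7.64-fold higher, SE 0.41) passed with any 1 tumour or array left out, Ank (-4.39) except without dKO tumour 2 (adjusted p = 0.0569). Krt7 (4.39), Crabp1 (3.61), Tslp (at least 29.3-fold lower), Slc14a1 (-3.78), Cldn8 (-3.76), Casd1 (-3.74) and Tceal8 (-3.52) passed but not in 3 to 10 of the leave-outs.

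Itga6, which marks the basal layer, fell to 2370 from 6193 (log2 -1.39, SE 0.26, adjusted p = 0.0248), as did Trp63 (-1.15, SE 0.24). Stress keratins Krt16 (7.77-fold, SE 0.59) and Krt17 (3.65-fold, SE 0.42) and Car9 (6.26-fold, SE 0.48) rose, and Usp18 (4.2-fold lower, SE 0.33) and Hmga2 (6.10-fold lower, SE 0.63) fell. Each of these calls failed in 2 to 7 of the leave-outs (adjusted p up to 0.0958 for Itga6, 0.105 for Trp63, 0.0967 for Krt16, 0.15 for Krt17, 0.0882 for Car9, 0.0661 for Usp18 and 0.147 for Hmga2). Cd34 (-0.49, adjusted p = 0.761) and Itgb1 (-0.53, SE 0.32, adjusted p = 0.287) did not pass.

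Leukocyte and macrophage markers rose in dKO tumours (5 higher, 0 lower and 7 not passing of 12, 10 higher alone, camera adjusted p = 3.01e-06, and 0.62 with an estimated correlation), among them Csf1r (4.76-fold), C1qa (4.82-fold) and C1qb (3.76-fold). These 3 failed in 5 to 6 of the leave-outs, with adjusted p up to 0.116. Fibroblast markers (3 of 11 higher, 3 alone; 0.00362, and 0.62 with an estimated correlation) and endothelial markers (1 of 2 higher, 2 alone; 0.036, and 0.62) shifted with them. Terminal differentiation shifted up with 0 members past the limma threshold over all genes or alone (adjusted p = 0.036, and 0.696 with an estimated correlation). Keratins (3 of 11 higher, 4 alone, adjusted p = 0.0975), hypoxia (1 of 15; 0.0938), cytokines (1 higher, 1 lower of 13; 0.0588) and basal genes (0 and 2 of 14, 3 lower alone; 0.412) did not pass.

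Between dKO and WT tumours 697 genes passed, 247 higher and 450 lower, which became 391 higher and 290 lower of 681 after quantile normalization, so the side with more genes depends on scaling. Of 2781 genes with an unadjusted p under 0.05, none passed in limma with only dKO and WT tumours in the fit (1495 unadjusted there) or with the macrophage marker mean as covariate (1426 unadjusted). For that reason 0 of 36 named genes passed under every alternative. From 46 to 1893 genes passed with 1 tumour or array left out: 1893 without WT tumour 2, 109 and 102 without dKO tumours 1 and 2, 84 without either epidermal progenitor array and 46 without either bulge array. Genes changed in both knock-out comparisons with WT numbered 44 higher and 51 lower for TbRII KO and dKO (9.03 and 11.3 expected, 5 opposite), 11 higher and 24 lower for FAK KO and dKO (0.641 and 2.24 expected, 0 opposite) and 4 higher and 21 lower for TbRII KO and FAK KO (0.877 and 1.15 expected, 1 opposite). Simulated unchanged groups gave a mean of 0.02 shared genes, which again leaves out the effects. The WT tumours are common to all 3 comparisons, and part of the excess may come from these shared controls.

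FAK loss in a TbRII KO background was measured by 2 dKO against 2 TbRII KO tumours. Ptk2 is not analysed here, and Tgfbr2, targeted in both, did not pass (-1.62, SE 0.51, adjusted p = 0.0746). Krt20 rose 91.9-fold (log2 6.52, SE 0.66, adjusted p = 0.000546, intensity 2555 against 27.8), Calcb 64.1-fold (log2 6.00, SE 0.54) and Il33 14.5-fold (log2 3.86, SE 0.37). Of the genes higher in TbRII KO than in WT tumours, several were low in dKO tumours: Mgp (80.1-fold lower, SE 0.35), Xist (79.6-fold, SE 0.51), Igfbp6 (59.2-fold, SE 0.57), S1pr3 (33.5-fold, SE 0.30), Bbs7 (87-fold, SE 0.37), Tenm2 (at least 66.6-fold), Kcnj15 (at least 44.1-fold) and H2-Eb1 (16.7-fold). Foxd1 was at least 32.4-fold lower (SE 0.20, adjusted p = 4.31e-06), Gata3 6.24-fold and the EMT regulator Zeb2 8.17-fold lower (SE 0.41). Each of these 14 genes passed under every alternative. Zeb1 fell by 2.62 (SE 0.32, adjusted p = 0.00152; 0.0729 with CD34high arrays alone), the Wnt ligand gene Wnt5a by 4.54 (SE 0.57) and Pdgfra by 1.83 (SE 0.29), while Ccn2 (16.5-fold, SE 0.57), Col4a1 (8.78-fold, SE 0.46), Ppbp (45.1-fold, SE 0.88) and Moxd1 (5.18) rose.

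Other epithelial genes rose in dKO over TbRII KO tumours, but not in some leave-outs. Krt7 was at least 64.9-fold higher (SE 1.12; adjusted p = 0.0732 without TbRII KO tumour 2), Cldn7 39.3-fold (SE 0.95; up to 0.0808 without TbRII KO tumour 2 or dKO tumour 1), Lamb3 7.04-fold (SE 0.53; up to 0.0924 without the same tumours), Krt17 5.17-fold (SE 0.42; up to 0.0676 without TbRII KO tumour 2 or dKO tumour 2) and Krt19 55.2-fold (SE 1.15; up to 0.074 without any of the 4 tumours). The differentiation regulators Grhl3 (4.04-fold; up to 0.142) and Ovol1 (5.03-fold; up to 0.135) failed without TbRII KO tumour 2 or either dKO tumour. Adm, a hypoxia target, rose 7.91-fold (0.0915 without TbRII KO tumour 2), Arg1 rose by 5.98 (up to 0.143) and Vim was 5.94-fold lower (SE 0.58; up to 0.128 without any of the 4 tumours). Cd34 (-0.62, adjusted p = 0.729), Itga6 (-0.59, adjusted p = 0.184) and Itgb1 (-0.62, adjusted p = 0.252) did not pass.

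Among lists, keratins rose (4 higher, 0 lower and 7 not passing of 11, 6 alone, camera adjusted p = 8.45e-05, and 0.0761 with an estimated correlation), and leukocyte markers rose beside them (2 of 12, 10 alone; 7.5e-06, and 0.549 with an estimated correlation). Melanocyte genes fell (2 of 2, 2 alone; 0.000804, and 0.159), Mlana by 3.26 (SE 0.26) and Mitf at least 6.55-fold lower (SE 0.25). Hypoxia (3 of 15 higher, 3 alone; 0.00308, and 0.549), terminal differentiation (2 of 18, 5 alone; 0.00846, and 0.549), TGF-beta response (3 of 12, 3 alone; 0.0494, and 0.318) and fibroblast genes (1 higher, 1 lower of 11, 2 and 1 alone; 0.0494, and 0.568) passed with the preset correlation only. Mesenchymal genes had 1 higher and 3 lower of 12 (adjusted p = 0.114), cytokines 4 and 1 of 13 (0.174) and basal genes 1 and 0 of 14 (0.0961). Integrins had 1 higher of 18 (0.402, a median of -0.03 that turned positive after quantile normalization and a mean of 0.05).

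Between dKO and TbRII KO tumours 1005 genes passed, 394 higher and 611 lower (470 and 469 of 939 after quantile normalization), and 16 of 54 named genes that passed did so under every alternative. With the macrophage marker mean as covariate 233 passed, 200 of them among the 1005. From 320 to 1695 passed with 1 tumour or array left out: 1695 without either WT tumour, 320 without TbRII KO tumour 2, 444 and 493 without dKO tumours 1 and 2, 648 without either epidermal progenitor array and 644 without either bulge array.

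**Figure D3:**
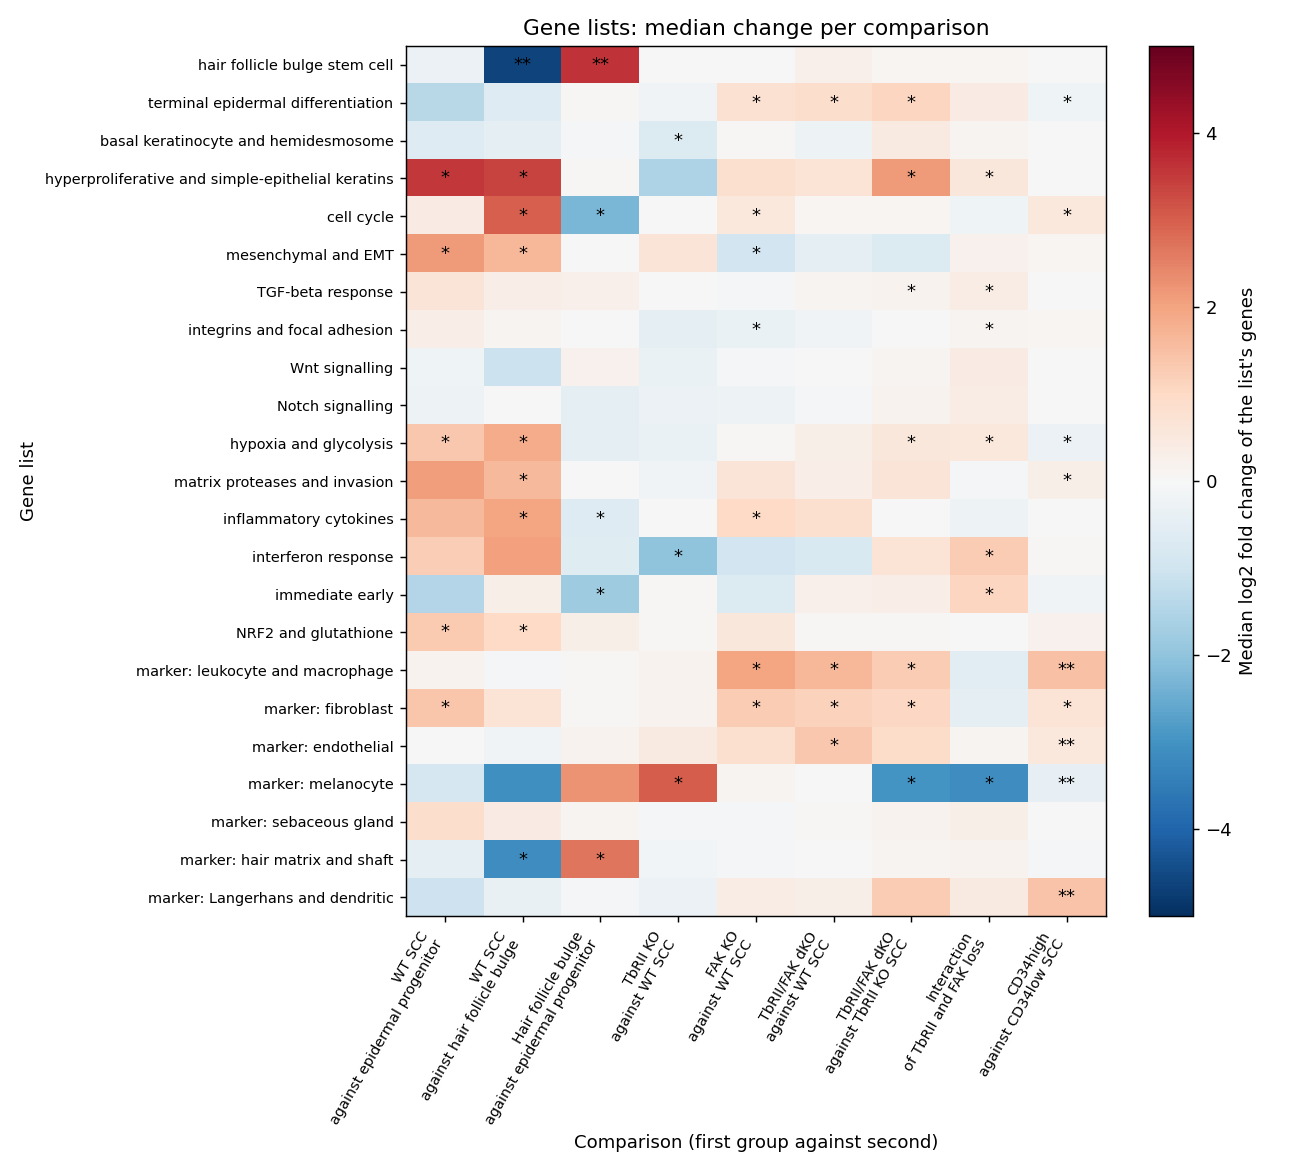
Median log2 change (colour) of 23 gene lists in 9 comparisons; 1 star marks a camera adjusted p under 0.05 with the preset correlation and 2 stars also with an estimated correlation. Bulge stem cell genes move in both comparisons with the bulge, and leukocyte markers rise in FAK KO, dKO and CD34high samples.

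Whether FAK loss acts differently with and without TbRII was tested as an interaction over 2 tumours of each of 4 genotypes, where positive values mean a higher level in dKO than the separate losses add up to. Calcb had the largest value (log2 14.34, SE 0.76, adjusted p = 5.67e-05), since it was low after either single loss and high in dKO tumours. The platelet chemokine gene Ppbp (9.19, SE 1.24), Krt20 (7.48, SE 0.94) and the claudin gene Cldn4 (6.27, SE 0.85) were positive as well. Negative values came from Xist (-11.25, SE 0.73), high after either single loss and low in dKO tumours, and from Igfbp6 (-7.92, SE 0.80), Tenm2 (-7.11, SE 0.74) and Bbs7 (-5.93, SE 0.52). Tenm2 was at the floor in WT and dKO tumours and in FAK KO tumour 2, and Calcb, Ppbp, Krt20 and Bbs7 were there in 1 tumour or more, so these sizes are not exact. These 8 genes passed under every alternative. With any 1 tumour or array left out, Thbd (-6.51, SE 1.10), Pdgfra (-2.87, SE 0.41), Zeb1 (-2.68, SE 0.45) and the latent TGF-beta binding protein gene Ltbp3 (3.38, SE 0.50) still passed. Other large values, Krt19 (8.83; adjusted p up to 0.0645 with 1 left out), Krt7 (7.65; 0.0959), Krt8 (6.92; 0.125), Cldn7 (6.86; 0.0889), Gjb2 (-7.02; 0.0798), Rps9 (-6.57; 0.111) and Mgst1 (-6.47; 0.109), failed in 4 to 9 of the leave-outs. Tgfbr2 (-1.89, SE 0.73, adjusted p = 0.17), Cd34 (1.41, adjusted p = 0.583), Itga6 (-0.28, adjusted p = 0.69) and Itgb1 (-0.60, adjusted p = 0.477) did not pass.

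Focal adhesion genes had positive interactions: the integrin gene Itga3 (2.68, SE 0.48, adjusted p = 0.0168), the kinase gene Src (2.01, SE 0.36, 0.0182) and the scaffold gene Bcar1 (2.03, SE 0.39, 0.0228), though Itga3 (up to 0.0546) and Src (up to 0.0593) failed without either dKO tumour and Bcar1 in 6 leave-outs (up to 0.0786). As lists, integrins and focal adhesion (3 higher, 0 lower and 15 not passing of 18, 3 alone, camera adjusted p = 0.0189, and 0.537 with an estimated correlation) and keratins (4 of 11, 4 alone; 0.0189, and 0.2 with an estimated correlation) shifted up. So did TGF-beta response (2 of 12, 3 alone; 0.0307, and 0.2), interferon (1 of 5; 0.0337, and 0.643), hypoxia (0 of 15 by limma, 1 lower alone; 0.0412, and 0.867) and immediate early genes (0 of 12 by limma; 0.0439, and 0.867). The pair of melanocyte genes Mlana (-3.21, SE 0.37) and Mitf (-3.02, SE 0.35) shifted down (0.00333, and 0.2 with an estimated correlation). Leukocyte markers had 0 of 12 past the limma threshold (adjusted p = 0.853). The median of all genes was -0.19 and moved to -0.06 after quantile normalization.

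The interaction passed in 405 genes, 182 positive and 223 negative (229 and 186 of 415 after quantile normalization), and 10 of 37 named genes that passed did so under every alternative. From 171 to 1144 genes passed with 1 tumour or array left out: 838 and 1144 without WT tumours 1 and 2, 188 without TbRII KO tumour 2, 203 and 214 without dKO tumours 1 and 2, 230 without FAK KO tumour 2, 171 without either epidermal progenitor array and 178 without either bulge array.

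CD34high and CD34low fractions of the same tumours address what travels with CD34 inside a tumour. Cd34 itself, used for the sort, was higher in the CD34high fraction of 8 of 8 tumours (mean log2 difference 2.94, SD 1.46, range 0.73 to 4.56; two-sided exact sign-flip p = 0.0078, the smallest that 8 tumours can give). The sort did not give equal Cd34 levels: the CD34high array of FAK KO tumour 2 read 33.2, near the floor, and the CD34low array of WT tumour 2 read 535, above the 472 of CD34high in WT tumour 1. Complement and macrophage genes rose beside it with the tumour as block: C1qa by 1.88 (SE 0.24), Tyrobp by 1.86 (SE 0.24), the receptor gene Csf1r by 1.76 (SE 0.27), C1qb by 1.73 (SE 0.26), Lyz2 by 1.62 (SE 0.20) and the mannose receptor gene Mrc1 by 1.01 (SE 0.12). Lower in CD34high fractions of 8 of 8 tumours were the transcription factor gene Sox4 (-0.84), Hs3st6 (-0.62) and Dnajb4 (-0.57). Mrc1, Sox4, Hs3st6 and Dnajb4 are outside the naming rule and were picked after the result with the block was seen. Itga6 (0.02, SE 0.14), Itgb1 (-0.01) and Tgfbr2 (-0.03) did not differ past the threshold (adjusted p = 1 each).

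Across lists, leukocyte and macrophage markers rose in CD34high fractions (0 of 12 over all genes by limma without the block, 11 higher alone, camera adjusted p = 1.33e-31, and 0.0432 with an estimated correlation), with a list mean of 1.36 (SD 0.77), higher in 8 of 8 tumours (two-sided exact p = 0.0078, 0.0898 after adjustment over the lists). FAK KO tumour 2, where the CD34high array was near the Cd34 floor, had the smallest Cd34 difference (0.73) and the largest list difference (2.33). Langerhans and dendritic markers (0 of 4, 4 alone, camera adjusted p = 5.36e-08, and 0.0432) were higher in 7 of 8 tumours (exact two-sided p = 0.0156, 0.0898 after adjustment over the lists). Endothelial markers (0 of 2, 1 alone, camera adjusted p = 0.0041, and 0.047) were also higher in 7 of 8 (exact two-sided p = 0.0234, 0.108 after adjustment). Melanocyte markers shifted down by camera (0 of 2, 2 alone; 0.000338, and 0.0432), but with a list mean of -0.42 (SD 0.81), higher in 3 of 8 tumours (two-sided exact p = 0.25). Mitf differed by -1.57 in TbRII KO tumours and by -0.15 to 0.12 in the other genotypes. Cell cycle genes shifted up with the preset correlation only, with a median of 0.51 and 24 of 24 positive (0 of 24 passing, also alone, camera adjusted p = 3.71e-20, and 0.0765 with an estimated correlation). Their mean was higher in 6 of 8 tumours (exact two-sided p = 0.0547, 0.18 after adjustment over the lists). Fibroblast markers (4.15e-07, and 0.172 with an estimated correlation), matrix proteases (0.0123, and 0.384), hypoxia (lower; 0.00473, and 0.55) and terminal differentiation (lower; 0.0284, and 0.546) passed with the preset correlation only. With the tumour as block no list passed with an estimated correlation (0.36 for leukocyte markers).

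Without the tumour block limma passed 0 of 9248 genes between fractions (359 with an unadjusted p under 0.05, smallest adjusted p = 0.0632). The count of 462 that this threshold would give by chance does not apply here, since this fit ignores the pairing of fractions. Among 100 labellings within tumours, chosen after the data were seen, 3 gave as many as 359, the real one included. With the block 52 of 9185 passed, 40 higher and 12 lower (1344 unadjusted), Cd34 among them (adjusted p = 0.0306). Of these, 29 were higher and 3 lower in 8 of 8 tumours, and 8 were on the leukocyte and macrophage list. A further 15 were among macrophage genes listed only after the data were seen. Without the block, leaving out 1 array gave 0 to 26 genes: 26 without dKO CD34low 1, 16 without TbRII KO CD34high 1, 9 without WT CD34low 2, 8 without dKO CD34high 2, 2 without WT CD34high 2 or FAK KO CD34low 1, and 1 without FAK KO CD34low 2.

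**Figure D4:**
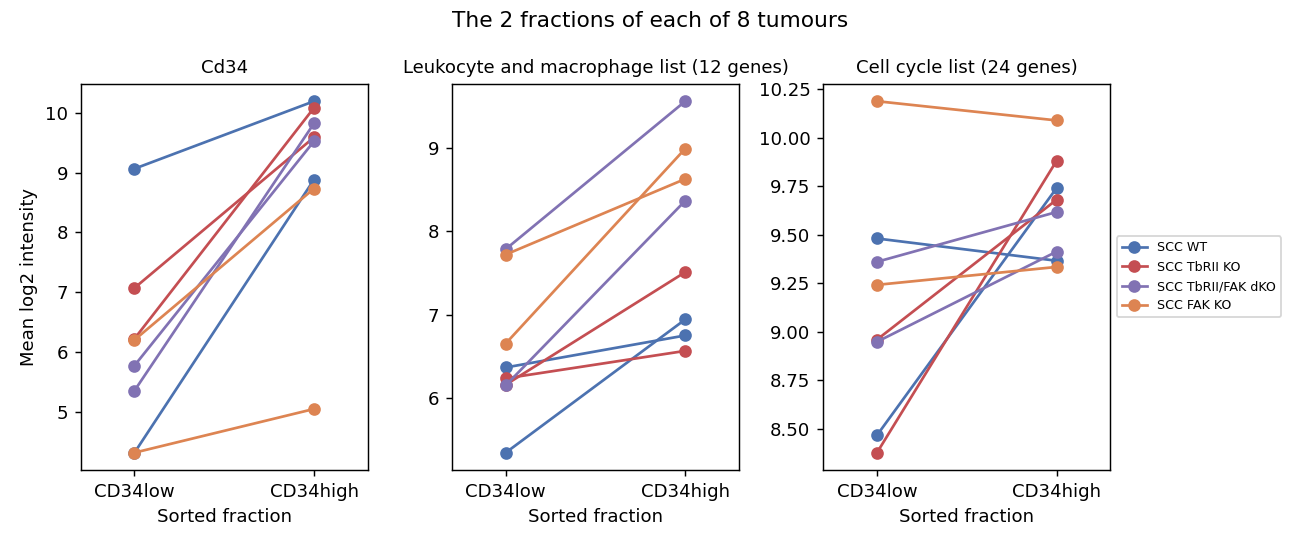
Level in the CD34low (left) and CD34high (right) fraction of each of 8 tumours, joined by a line, for Cd34 and for the means of the leukocyte and macrophage list (12 genes) and the cell cycle list (24 genes), all in log2 intensity. Cd34 and the macrophage list rise in 8 of 8 tumours, the cell cycle list in 6 of 8.

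The moderated F test of genotype on the fraction difference passed in 2 of 9185 genes (1009 unadjusted). Uts2, a vasoactive peptide gene, was lower in the CD34high fraction of the TbRII KO tumours (-3.01 and -3.27) and at the floor of both fractions elsewhere (adjusted p = 0.0098). Adgrd1 showed the same form (-2.34 in tumour 1, and a fall from 92.2 to the floor in tumour 2, adjusted p = 0.0424). At the floor no fraction difference can be seen and no spread is added. These 2 results therefore show detection in TbRII KO tumours only, and do not decide whether the fraction difference depends on genotype. No gene passed in limma when dim genes were not tested (0 genes, 627 unadjusted) or in the interaction over 20 arrays without a block (0 genes, 163 unadjusted). Leaving out 1 tumour gave 0 to 15 genes, 15 without WT tumour 2 and 0 without either TbRII KO tumour, either dKO tumour or FAK KO tumour 2.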

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

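The interaction contrast, the moderated F test and the list test of mesenchymal genes were planned, and the other tests in this part were chosen only after the result was seen. The effect of FAK loss differed between tumours with and without TbRII in 405 genes by the interaction contrast. The moderated F test of genotype on the fraction difference passed in 2 genes, both at the floor outside TbRII KO tumours, where no difference could be seen.

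Xist was low in WT tumours (98 and 62) and dKO tumours (39 and 122) and high in TbRII KO tumours (3814 and 7868) and FAK KO tumours (2507 and 2250), so the interaction falls along a line that sex of the tumour cells or X inactivation could draw. If that difference had caused the TbRII KO against WT calls, these genes would move alike in FAK KO tumours. Their signed median there was 0.356 (quartiles 0 to 0.898), against 1.81 in TbRII KO tumours themselves. The genes were chosen because they passed in TbRII KO tumours, which raises the 1.81, so the gap alone does not decide. In all, 71.6% had the same sign, a share that the WT tumours common to both comparisons raise. No value of that share without a common effect was computed. The Y-linked genes Eif2s3y and Kdm5d were above the floor only in WT tumour 2 (268 and 129) and dKO tumour 2 (84 and 29). A sex difference or loss of an X or Y chromosome stays open. With 2 tumours per genotype, origin of a tumour and genotype remain confounded for single genes such as Calcb.

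Leukocyte and macrophage genes were higher in CD34high fractions and in FAK KO and dKO tumours. Macrophage RNA carried over into the fractions could do this, although the sort was on reporter-positive cells. A second set of 23 macrophage genes rose by a median of 1.32 in CD34high fractions (1.48 for the fixed list), 1.70 in FAK KO and 1.26 in dKO tumours, but it was listed after the data were seen, 15 of the 23 are among the 52 genes that passed between fractions, and 2 members of each list exceed 100 in both normal populations. For a lower share of tumour cells that raises every other cell type alike, the 2 lists were compared. Macrophage minus fibroblast list averaged 0.73 (SD 0.42), positive in 8 of 8 tumours (two-sided exact sign-flip p = 0.0078, the smallest possible). Equal added RNA gives equal log2 rises only from equal starting levels. In CD34low fractions the fibroblast list mostly started higher (6.96 against 5.35 in WT tumour 1, but 6.34 against 6.37 in WT tumour 2), so this difference does not decide. The macrophage genes alone cannot tell carry-over from expression by tumour cells, since both would raise the set alike. Xist, low in WT and dKO tumours, could mark added cells that express it. From CD34low to CD34high it rose in WT tumour 1 (46.4 to 205.2) and dKO tumour 2 (47.2 to 315.2). It hardly moved in WT tumour 2 (60.4 to 62.9). In dKO tumour 1 it went from 33.2 to 45.3 while the macrophage list mean rose from 7.78 to 9.56. This use of Xist was not tested, and the question stays open.

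Zeb1, Zeb2 and S100a4 rose in TbRII KO tumours while some epithelial genes fell. Fibroblast RNA carried over might explain this. The fibroblast list had a median of -1.30 in TbRII KO minus FAK KO tumours while Zeb1 was higher by 2.50 (SE 0.32). Zeb1 thus did not follow the list as a whole, but some members went the other way. Pdgfra read 183 and 244 in TbRII KO tumours, against 91.7 and 83.2 in FAK KO and 43.7 and 41.7 in WT tumours. Against WT, where Zeb1 rose, the list median was 0.17, so fibroblast RNA is not excluded. For melanocyte RNA carried over into TbRII KO tumours, 0 of the melanocyte genes sought beyond Mlana and Mitf were left to analyse. Dim or steady genes had been filtered out before deposit, and whether this removed them is not known. Carry-over therefore cannot be told apart from a change in the tumour cells. A shift of TbRII KO tumour cells to a mesenchymal state stays an undecided hypothesis: the mesenchymal and EMT list as a whole did not pass (camera adjusted p = 0.596), and no test here separates cell state from cell mixture.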

How the results depend on the processing

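The tests reported here were planned, except the marker covariate and leaving out tumours in the genotype test of fractions, which were chosen after seeing the data. Counts of passing genes moved by over 1.5 times as follows, and the cause was not tested unless stated. Without the dimmest 40% of genes, which tests fewer genes, 1650 passed for WT SCC against epidermal progenitor, 2059 against bulge, 432 for bulge against epidermal progenitor, 275 for TbRII KO, 24 for FAK KO and 360 for dKO against WT, 373 for dKO against TbRII KO, 139 for the interaction and 0 for genotype by fraction (627 unadjusted). With only the groups compared in the limma fit, bulge against epidermal progenitor rose to 3551, while WT SCC against epidermal progenitor fell to 1505, against bulge to 2327, TbRII KO to 69, FAK KO to 0 (533 unadjusted), dKO against WT to 0 (1495 unadjusted) and the interaction to 69. With the 20 arrays as separate units, which treats fractions of 1 tumour as replicates, TbRII KO gave 1652, FAK KO 745, dKO 2764, dKO against TbRII KO 2339 and the interaction 1625. CD34low arrays alone gave 92 for dKO against WT and 682 for the interaction, and CD34high arrays alone 292 for TbRII KO, 1151 for dKO, 667 for dKO against TbRII KO and 171 for the interaction. With replicate number as block FAK KO gave 39; no label pairs numbers across groups, and deviations of equal numbers in different groups correlated at -0.14 to 0.42, over 0.1 in some pairs of groups (0.152 for WT and FAK KO) and not in others, so pairing across groups was not taken and stays open.

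The mean of the leukocyte and macrophage markers as covariate gave 16 genes for FAK KO (821 unadjusted, 6 shared with the 70), 0 for dKO against WT (1426 unadjusted) and 233 for dKO against TbRII KO (200 shared with the 1005); Dkk3 in dKO against WT changed from -2.23 to 0.093 (adjusted p 0.0489 to 0.951), the 1 reversed value among named genes. Between fractions, quantile normalization gave 1 gene and the tumour as replicate block 52, since the block removes differences between tumours. For genotype by fraction, the interaction over 20 arrays without a block gave 0 (163 unadjusted). Of 56 list shifts that passed with the preset correlation, 6 passed with an estimated correlation.

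Leaving out 1 tumour or array gave 1320 to 3343 genes for WT SCC against epidermal progenitor, 2124 to 4050 against bulge, 511 to 1445 for bulge against epidermal progenitor, 283 to 1482 for TbRII KO, 9 to 555 for FAK KO, 46 to 1893 for dKO against WT, 320 to 1695 for dKO against TbRII KO, 171 to 1144 for the interaction, 0 to 26 between fractions and 0 to 15 for genotype by fraction. Most of the higher counts came without WT tumour 2. Of 404 named gene calls, 203 passed under every alternative and 201 failed under at least 1. Values at the floor limit the folds of dim genes, and the share at the floor does not limit bright ones. Groups at the floor also add no spread to the estimate shared by all groups. The SE and p-values of genes such as Foxd1 (at the floor outside TbRII KO tumours) and Lgr5 (at the floor outside the bulge) can therefore be too small.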

Other observations

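The models and the counts with and without the tumour block were planned, while the gene lists, their tests, the genes named and the relabellings in this part were chosen only after the result was seen. Epithelial junction genes (27 of 30 measured) fell in TbRII KO tumours: 12 lower, 0 higher, 14 lower adjusted over the list alone, median -1.31, camera adjusted p = 1.75e-08, and 0.269 with an estimated correlation. The cadherin gene Cdh1 (-1.48, adjusted p = 0.0084), Epcam (-2.39, 0.010) and Cdh3 (-1.33, 0.019) were among them. In dKO over TbRII KO tumours the same list rose (14 higher, 0 lower, 19 alone, median 1.5; 1.69e-12, and 0.229 with an estimated correlation), and in the interaction it was positive (12 higher, 1 lower; 8.59e-11, and 0.229). All of these tests use the TbRII KO tumours whose low values prompted the list. The p-value for TbRII KO against WT restates what prompted it, and the other tests are no separate evidence. FAK KO tumours did not show a shift (1 higher; 0.391), and dKO over WT tumours had 2 higher and 1 lower (0.0143, and 0.637 with an estimated correlation). Collagen genes (18 of 21 measured) split in TbRII KO tumours into 4 higher, Col5a1 (3.53) and Col6a2 (2.14) among them, and 2 lower, and they rose in bulge over epidermal progenitors (8 higher, 1 lower; 9.37e-06, and 0.269 with an estimated correlation). With the preset correlation they also shifted up in FAK KO (0 higher, 1 lower, median 1.20, adjusted p = 0.00442) and dKO over WT tumours (1 higher, median 0.81, 0.00241) and in CD34high fractions (0 higher by limma, median 0.29, 0.00228), where fibroblast and macrophage markers rose too, and in none of these 3 with an estimated correlation (0.448 each).

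A second macrophage set (23 of 28 measured) had 2 members higher in FAK KO (18 alone; 9.27e-16, and 0.269 with an estimated correlation) and 9 in dKO over WT tumours (17 higher and 1 lower alone; 1.24e-09, and 0.407). Between fractions 21 of 23 were higher adjusted over the list alone (6.64e-58, and 0.0264 with an estimated correlation).

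Relabelling fractions within tumours tested the counts between CD34high and CD34low. Without the block, 100 of 100 relabellings gave at least the real 0 genes (highest other 1), an outcome that a real count of 0 fixes, so this says nothing about chance. At an unadjusted p under 0.05 the real labels gave 359 genes, 3 of 100 labellings, the real one included, gave as many, and the highest other gave 470. With the tumour as block the real labels gave 52 genes and the highest other 5, so 1 of 100, the real one, was as large. This is the smallest share that 100 labellings can give, and it argues against chance for that count.

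Tumours of 1 genotype differed in the ribosomal protein gene Rps9, which read 310 and 466 in WT tumours and 670 in dKO tumour 1, against 8297 to 14417 in the other tumours and normal cells. Bbs7, by contrast, followed genotype, with 1415 and 2254 in TbRII KO tumours and at most 48.1 in the other tumours. The 5' to 3' ratio of Gapdh, a measure of RNA integrity, had a median of 0.824 in SCC arrays, 0.640 in epidermal progenitors and 0.444 in bulge cells, so RNA quality and cell type change together in comparisons with normal cells. Among tumours it was lower in FAK KO (0.746, range 0.603 to 0.798) than in TbRII KO (0.887, range 0.808 to 0.910). WT was at 0.842 (range 0.602 to 0.947) and dKO at 0.851 (range 0.546 to 0.874), so RNA quality is not set apart from genotype there either.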
